A study of Salix matsudana with 18 samples.

How the data were processed

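Total RNA from roots of LCW and HCW willow cuttings at 0, 1 and 4 d of 100 µM CdCl2 was sequenced by the authors on an Illumina platform, with 3 libraries in each of 6 groups. Per the labels, the authors used CASAVA 1.8, RSEM 1.2.15 and Bowtie2, the last without a version. The values deposited by the authors are FPKM with 2 decimals, with a separate file for each library over the same 419,256 transcript clusters, and neither the assembler nor a genome build is named. A deposited annotation gives each cluster its length in bases (201 to 16,896) and best hits in protein and nucleotide databases. Each FPKM column sums to 2,790,000 to 3,100,000. The labels give no batch, and every library was assigned to its group from its genotype and treatment fields.

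FPKM is no count, so the test planned for counts was replaced by the fallback fixed with it before the data were examined. That fallback is limma-trend with robust empirical Bayes (limma 3.58.1, R 4.3.3) on log2 of FPKM plus a pseudocount of 1. All 18 libraries entered 1 fit with 6 group means, and contrasts gave 9 comparisons: 1 d and 4 d against 0 d within each genotype, HCW against LCW at each time, and the HCW change minus the LCW change at 1 d and at 4 d. Clusters with at least 1 FPKM in at least 3 libraries were tested, 234,780 in all. Calls are two-sided at a Benjamini-Hochberg adjusted p under 0.05 over the clusters of a comparison. The same choices also set the overlap of LCW and HCW calls per direction, given beside the number expected for independent calls. Values were handled with data.table (1.17.8), Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

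The 44 gene lists are search patterns on the protein description of a cluster (Swiss-Prot where given, otherwise the NR hit), 25 of them core, and include markers of other cell types and of green tissue. Of the clusters tested, 56.3% had a Swiss-Prot hit and 81.5% an NR hit. Lists were tested with limma camera at its preset correlation of 0.01 between members, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with a correlation estimated from the data. Of the calls at the preset correlation, 11 of 24 held with the estimated correlation in LCW at 1 d, 3 of 19 in LCW at 4 d, 1 of 26 in HCW at 1 d and 9 of 24 in HCW at 4 d, and none held in the comparisons between genotypes.

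The clusters named in the text come from a rule set in advance. For each comparison it takes the 5 called clusters with the largest rise and the 5 with the largest fall, at an average of at least 10 FPKM, with a named plant protein and no overlap between the groups' libraries, and the called member of each core list with the lowest p-value in each direction. For the differences of responses it takes list members only. After the data were seen this was narrowed to clusters of at least 300 bases without a bird hit, mostly with a protein total called in the same direction, and 165 named results were examined further. The text names mainly those still called with each library left out in turn, 138 of the 165. Where a cluster was at 0 in every library of either group of a comparison, its values are given and no fold change. A difference of responses that involves such a group is given with the pseudocount of 1, which sets its size.

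Depth was recovered from the values. FPKM times cluster length steps in multiples of a single fragment, and clusters of 400 to 700 bases gave totals of 12,970,000 to 18,480,000 fragments per library and mean fragment lengths of 227.1 to 263.8 bases. As a check, 73.2 to 77.0% of low values fell within 0.1 of a whole fragment, where evenly spread values would give 20%. The totals were fitted on clusters of the same lengths, so part of this was built in, and other lengths were not checked. On a cluster of 1000 bases, 3 fragments correspond to 0.21 to 0.304 FPKM, which is the level below which a listed 0 says little, for counting error only. The tests were checked on simulated data with the same design. With 20,000 changed clusters, 78.2% of 4-fold and 39.3% of 2-fold changes at a mean of 10 FPKM or more were called, 41.4% and 9% at lower means, and 4.7% of the calls were of unchanged clusters. With 200 changed clusters, 57.7% of 4-fold and 8.3% of 2-fold changes at 10 FPKM or more were called, 8.1% and 0% at lower means, and 34.3% of the calls were of unchanged clusters.

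Alternatives fixed before the data were examined were quantile normalization, no filter and a stricter filter (1 FPKM in 9 libraries), replicate number as a block, only the compared groups in the fit, a 2-fold minimum, clusters with a land plant hit only, FPKM summed per best-hit protein, a pseudocount of 0.1, and each library left out. Alternatives added after seeing the data were limma-voom on fragments rebuilt from FPKM, length and depth, median-ratio scaling, leaving out bird-hit clusters, clusters of at least 300 bases, and leaving out LCW 0 d library 1 and LCW 1 d library 1 together. Near-identical clusters were searched with BLAST+ 2.17.0 at 95% identity over at least 150 bases, for 3000 called clusters per comparison. No library was left out of the main comparisons.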

Results

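Root RNA was sequenced from hydroponic stem cuttings of 2 willow genotypes, abbreviated LCW and HCW in the labels. LCW is Salix matsudana, and HCW is its form umbraculifera. Roots stood in 100 µM CdCl2 for 0, 1 or 4 d, which gave 6 groups of 3 libraries and 18 libraries in all. Each library lists FPKM, fragments per kilobase scaled to the library total, for 419,256 assembled transcript clusters. LCW libraries held 14,680,000, 14,110,000 and 14,780,000 fragments at 0 d, 15,220,000, 16,920,000 and 13,860,000 at 1 d, and 14,620,000, 13,400,000 and 14,670,000 at 4 d. HCW libraries held 14,150,000, 14,010,000 and 15,640,000 fragments at 0 d, 18,480,000, 15,670,000 and 15,590,000 at 1 d, and 15,640,000, 12,970,000 and 13,550,000 at 4 d. These totals were recovered from the spacing of low values, and a single fragment on a cluster of 1000 bases gave 0.0699 to 0.1015 FPKM. Libraries of the same group correlated with r of 0.828 to 0.869 across clusters, and libraries of different genotypes with r of 0.662 to 0.753, and clusters are not independent replicates.

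The study concerns metal transport and the ascorbate-glutathione pathway in genotypes that differ in how much cadmium they take up and withstand. Changes below are log2 differences of FPKM plus 1, given with their standard error, and group levels are mean FPKM with SD, n = 3 libraries per group. Gene lists were fixed before the data were examined. For each list, the members called over all clusters are followed by the counts adjusted over the list alone, and the p-value is from the list test with a preset correlation between members. No untreated roots were sampled at 1 or 4 d, so exposure to CdCl2 and elapsed time are not separated in any comparison with 0 d. The labels do not say whether the 3 libraries of a group come from separate plants, and the p-values cover only the spread between libraries.

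The LCW comparison of 1 d with 0 d asks what changed in these roots within a day of exposure. Transcripts of glutathione synthesis, the route to the main thiol that binds cadmium in plants, were higher at 1 d. Of 39 clusters in that list, 16 rose and 1 fell, or 23 and 1 adjusted over the list alone (adjusted p = 2.09e-12). Glutamate-cysteine ligase, its rate-limiting enzyme (Cluster-36310.42397), reached 138.37 ± 20.04 against 37.17 ± 7.91 FPKM, a change of 1.88 ± 0.21. A protease inhibitor of the trypsin and hageman factor type (Cluster-36310.37953) reached 1367.84 ± 280.61 from 1.19 ± 2.07 FPKM (adjusted p = 1.41e-06). Peroxidase 12 (Cluster-36310.171048) rose from 48.35 ± 8.18 to 1058.66 ± 166.42 FPKM, by 4.43 ± 0.3. The 18.5 kDa class I heat shock protein (Cluster-36310.283336), a small chaperone, was listed at 0 in every 0 d library and at 62.51, 42.49 and 55.62 FPKM at 1 d.

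Among transporters of LCW at 1 d, the ABCC family, which includes vacuolar pumps for glutathione conjugates, had 53 of 252 members higher and 5 lower, or 63 and 5 adjusted over the list alone (adjusted p = 1.2e-09). ABCC member 10 (Cluster-36310.283797) rose by 3.48 ± 0.36. Heavy metal P-type ATPases had 24 of 153 members higher and 1 lower, or 27 and 3 adjusted over the list alone (adjusted p = 3.42e-07), and the copper pump HMA5 (Cluster-36310.30311) reached 36.0 ± 9.39 from 5.69 ± 0.96 FPKM. Another HMA5 cluster (Cluster-36310.204559) fell by 1.25 ± 0.33, to 11.87 ± 2.68 from 29.39 ± 5.17 FPKM, and was not called without LCW 0 d library 1 (adjusted p = 0.05), LCW 0 d library 2 (adjusted p = 0.082) or LCW 1 d library 3 (adjusted p = 0.0959). ZIP transporters, which import zinc and iron, had 18 of 92 members higher and 3 lower, or 23 and 5 adjusted over the list alone (adjusted p = 8.06e-05, and adjusted p = 0.0674 with an estimated correlation). Zinc transporter 1 (Cluster-36310.62809) rose by 1.81 ± 0.32, while probable zinc transporter 10 (Cluster-36310.174341) fell by 3.27 ± 0.53. The metal transporter Nramp5 (Cluster-36310.252349) went from 22.05 ± 12.02 to 0.34 ± 0.59 FPKM, while another Nramp5 cluster (Cluster-36310.98035) was at 10.32, 11.44 and 12.09 FPKM at 0 d and 15.27, 12.82 and 10.54 FPKM at 1 d. Iron deficiency genes had 0 of 68 members higher and 27 lower, or 1 and 29 adjusted over the list alone (adjusted p = 2.37e-09, and adjusted p = 0.0674 with an estimated correlation). The water channel PIP2-8 (Cluster-36310.159708) dropped to 168.6 ± 15.59 from 909.53 ± 123.39 FPKM. A cluster for HIPP26, a metal-binding isoprenylated protein (Cluster-36310.38336), was listed at 0 in all 3 LCW libraries at 0 d and at 51.14, 50 and 62.64 FPKM at 1 d.

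In the redox pathways of LCW at 1 d, the ascorbate-glutathione cycle had 20 of 165 members higher and 8 lower, or 22 and 11 adjusted over the list alone, and its list test did not pass (adjusted p = 0.0858). Without LCW 0 d library 1 that test gave adjusted p = 0.0492. Monodehydroascorbate reductase, which regenerates ascorbate (Cluster-36310.149052), went from 54.78 ± 14.36 to 161.45 ± 26.0 FPKM. A probable cytoplasmic isoform of it (Cluster-36310.52566) was at 32.74, 23.2 and 32.41 FPKM at 0 d and lower at 1 d, at 12.69, 13.08 and 15.34 FPKM. Ascorbate synthesis had 17 of 139 members higher and 5 lower, or 19 and 5 adjusted over the list alone (adjusted p = 0.0182, and adjusted p = 0.142 with an estimated correlation), and without LCW 0 d library 3 its adjusted p was 0.133. Inositol oxygenase 2 in that list (Cluster-36310.36121) rose by 4.38 ± 0.39. Mannose-1-phosphate guanylyltransferase 1 (Cluster-36310.148991) went the other way, from 115.1, 195.59 and 104.85 FPKM at 0 d to 47.34, 56.65 and 61.57 FPKM at 1 d. Sulfate assimilation and cysteine synthesis had 48 of 229 members higher and 4 lower, or 52 and 6 adjusted over the list alone (adjusted p = 1.76e-07). Glutathione S-transferases had 79 of 309 higher and 13 lower, or 90 and 21 adjusted over the list alone (adjusted p = 3.46e-08), although member F12 (Cluster-36310.157647) fell by 5.4 ± 0.48. Superoxide dismutases and catalases had 0 of 117 higher and 16 lower, or 1 and 16 adjusted over the list alone (adjusted p = 0.00666). Within that list, Cu-Zn superoxide dismutase 2 (Cluster-36310.185708) went from 148.53 ± 21.43 to 20.3 ± 7.66 FPKM.

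Heat shock proteins had 136 of 452 members higher and 11 lower in LCW at 1 d, or 153 and 14 adjusted over the list alone (adjusted p = 2.94e-18). The jasmonate pathway list had 88 of 341 higher and 7 lower, or 104 and 12 adjusted over the list alone (adjusted p = 6.25e-09), and a 12-oxophytodienoate reductase (Cluster-36310.280645) rose by 5.91 ± 0.45. Clusters for ACC oxidase, the last enzyme of ethylene synthesis, moved both ways: Cluster-36310.282665 rose by 5.98 ± 0.37 and Cluster-36310.166036 fell by 3.92 ± 0.49. Of lignin-pathway enzymes, cinnamoyl-CoA reductase 1 (Cluster-36310.257161) rose by 3.03 ± 0.3, and shikimate O-hydroxycinnamoyltransferase (Cluster-36310.201909) fell by 3.7 ± 0.29. Photosynthesis proteins, a marker of green tissue or algae, had 1 of 472 higher and 223 lower, or 2 and 274 adjusted over the list alone (adjusted p = 3.79e-40). Cell division markers had 9 of 643 higher and 51 lower, or 9 and 47 adjusted over the list alone (adjusted p = 0.00266, and adjusted p = 0.352 with an estimated correlation), and the call was lost without LCW 0 d library 2 (adjusted p = 0.0724) or LCW 1 d library 1 (adjusted p = 0.0508).

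Of 234,780 clusters tested, limma called 24,398 in LCW at 1 d, 12,070 higher and 12,328 lower, a balance that turned to 14,353 and 10,549 with median-ratio scaling, chosen after the data were seen, and to 13,077 and 11,537 with quantile normalization. With only these 6 libraries in the fit the count was 9,989, and with FPKM summed per best-hit protein it was 13,108 of 61,204 proteins, which ended the list calls of iron deficiency genes (adjusted p = 0.0569) and of superoxide dismutases and catalases (adjusted p = 0.0544). Clusters whose best nucleotide hit is a bird took 0.2431, 0.0756 and 0.0851% of fragments in the LCW 0 d libraries and 0.084% in LCW 1 d library 1, against 0.0003 to 0.0011% elsewhere. Leaving those clusters out gave 24,161 calls, and leaving out LCW 0 d library 1 and LCW 1 d library 1 together gave 17,423.

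**Figure D1:**
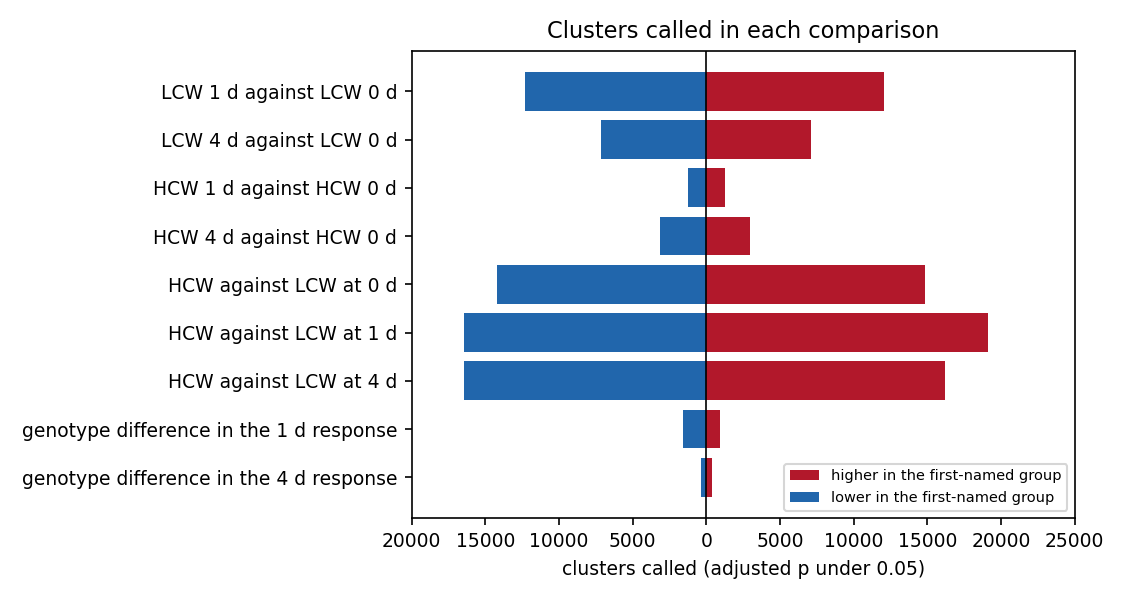
Clusters called in each comparison (horizontal axis, number of clusters at an adjusted p under 0.05), higher to the right and lower to the left in the first-named group. LCW at 1 d has 12,070 higher and 12,328 lower (14,353 and 10,549 with median-ratio scaling), and HCW at 1 d has 1,254 higher and 1,269 lower.

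The LCW comparison of 4 d with 0 d asks which changes were present after the longer exposure. Another trypsin and hageman factor inhibitor (Cluster-36310.287305) stood at 760.4 ± 162.29 against 4.3 ± 4.63 FPKM, a change of 7.54 ± 0.5 (adjusted p = 1.11e-06). Zinc transporter 5 (Cluster-36310.575) rose from 0.31 ± 0.49 to 19.65 ± 3.52 FPKM, and ZIP transporters as a list had 18 of 92 members higher and 1 lower, or 30 and 2 adjusted over the list alone (adjusted p = 8.19e-08). The aquaporin PIP2-4 (Cluster-36310.145795) went from 515.76 ± 42.17 to 2498.86 ± 591.52 FPKM, while PIP2-7 (Cluster-36310.158760) fell by 1.79 ± 0.2. A type 2 metallothionein, a small cysteine-rich metal binder (Cluster-36310.160393), reached 856.8 ± 130.52 from 150.99 ± 71.18 FPKM. Another cluster, metallothionein-like protein 2 (Cluster-36310.160394), did not rise, at 728.46, 556.74 and 642.77 FPKM at 0 d and 621.7, 648.58 and 739.09 FPKM at 4 d. Ferric reduction oxidase 4, a surface iron reductase (Cluster-36310.160755), dropped to 4.53 ± 0.4 from 79.63 ± 9.19 FPKM.

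Iron deficiency genes in LCW at 4 d had 2 of 68 members higher and 19 lower, or 2 and 27 adjusted over the list alone (adjusted p = 2.32e-10, and adjusted p = 0.0779 with an estimated correlation). Nicotianamine synthase (Cluster-36310.85100), which makes a metal chelator, went the other way in that list, by 2.64 ± 0.56. Sulfate transporter 3.1 (Cluster-36310.35197) rose by 3.36 ± 0.6, and the root uptake transporter 1.2 (Cluster-36310.147405) fell by 1.51 ± 0.3. Nramp5 (Cluster-36310.252349) stood at 0.29 ± 0.25 FPKM, and ABCC member 9 (Cluster-36310.268414) at 25.89 ± 0.69 against 9.2 ± 1.99 FPKM. Glutathione synthesis had 6 of 39 members higher and 0 lower, or 10 and 0 adjusted over the list alone (adjusted p = 0.000206, and adjusted p = 0.105 with an estimated correlation). Glutathione S-transferases had 50 of 309 higher and 14 lower, or 71 and 18 adjusted over the list alone (adjusted p = 0.000196, and adjusted p = 0.096 with an estimated correlation). The ascorbate-glutathione cycle had 6 of 165 higher and 5 lower, or 7 and 8 adjusted over the list alone (adjusted p = 0.552). Ascorbate synthesis had 9 of 139 higher and 2 lower, or 10 and 2 adjusted over the list alone (adjusted p = 0.0221, and adjusted p = 0.197 with an estimated correlation), and its call ended without LCW 0 d library 3 (adjusted p = 0.158) or LCW 4 d library 1 (adjusted p = 0.0789). Superoxide dismutases and catalases had 5 of 117 higher and 14 lower, or 7 and 19 adjusted over the list alone (adjusted p = 0.00157).

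Flavonoid enzymes in LCW at 4 d had 65 of 351 members higher and 16 lower, or 121 and 24 adjusted over the list alone (adjusted p = 7.68e-11, and adjusted p = 0.0655 with an estimated correlation). The proteasome, which degrades tagged proteins, had 61 of 510 higher and 8 lower, or 103 and 11 adjusted over the list alone (adjusted p = 1.07e-07, and adjusted p = 0.0655 with an estimated correlation). Laccase-14, which polymerises lignin units (Cluster-36310.58081), rose by 4.01 ± 0.41, and ACC oxidase 1 (Cluster-36310.166036) fell by 5.11 ± 0.49. Photosynthesis proteins had 1 of 472 higher and 213 lower, or 2 and 286 adjusted over the list alone (adjusted p = 4.02e-60). Cell division markers had 34 of 643 higher and 33 lower, or 49 and 38 adjusted over the list alone (adjusted p = 0.00182, and adjusted p = 0.406 with an estimated correlation), and the call ended without LCW 0 d library 1 (adjusted p = 0.151). In total 14,225 clusters were called, 7,074 higher and 7,151 lower, and leaving out bird-hit clusters gave 13,811. The count was 5,136 with only these libraries in the fit, 9,400 without LCW 4 d library 2 and 9,388 without LCW 4 d library 3. For summed proteins it was 9,024, 14.74% of those tested against 6.06% of clusters. The fit of these libraries alone ended the calls of Cluster-36310.35197 (adjusted p = 0.123), Cluster-36310.85100 (adjusted p = 0.101) and Cluster-36310.160393 (adjusted p = 0.0614). A pseudocount of 0.1 ended that of Cluster-36310.85100 (adjusted p = 0.0554), and limma-voom on rebuilt fragments, chosen after the data were seen, that of Cluster-36310.147405 (adjusted p = 0.09).

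The HCW comparison of 1 d with 0 d asks the same of the other genotype. The vacuolar water channel TIP1-1 (Cluster-36310.160925) fell from 613.24 ± 83.23 to 143.41 ± 21.5 FPKM, by 2.09 ± 0.23 (adjusted p = 0.000496). The first reductive enzyme of sulfate assimilation, APS reductase 1 (Cluster-36310.159650), rose from 99.6 ± 32.31 to 281.98 ± 23.68 FPKM. Glutathione S-transferase U3 (Cluster-36310.45602) went from 5.08 ± 0.98 to 82.58 ± 40.62 FPKM, and peroxidase 52 (Cluster-36310.66170) from 3.75 ± 1.95 to 102.59 ± 51.83 FPKM. ABCC member 9 (Cluster-36310.268414) rose by 1.23 ± 0.18, and the ethylene response factor ERF114 (Cluster-36310.270645) by 4.0 ± 0.42.

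As a list, aquaporins in HCW at 1 d had 1 of 269 members higher and 19 lower, or 5 and 37 adjusted over the list alone (adjusted p = 2.54e-07, and adjusted p = 0.0827 with an estimated correlation). Heat shock proteins had 22 of 452 higher and 1 lower, or 60 and 2 adjusted over the list alone (adjusted p = 2.83e-12). Glutathione synthesis had 1 of 39 higher and 0 lower, or 12 and 1 adjusted over the list alone (adjusted p = 4.99e-07, and adjusted p = 0.0827 with an estimated correlation). ABCC transporters had 8 of 252 higher and 0 lower, or 18 and 0 adjusted over the list alone (adjusted p = 7.17e-07, and adjusted p = 0.103 with an estimated correlation). Iron deficiency genes had 1 of 68 higher and 7 lower, or 1 and 17 adjusted over the list alone (adjusted p = 9.15e-12, and adjusted p = 0.0827 with an estimated correlation). The ascorbate-glutathione cycle had 3 of 165 higher and 0 lower, both over all clusters and adjusted over the list alone (adjusted p = 0.381). For ascorbate synthesis no member of 139 was called over all clusters, with 3 higher and 1 lower adjusted over the list alone, a median of -0.013, a mean of 0.049 and adjusted p = 0.774. Photosynthesis proteins had 0 of 472 higher and 43 lower, or 1 and 140 adjusted over the list alone (adjusted p = 2.36e-32, and adjusted p = 0.0827 with an estimated correlation). The call of 2,523 clusters, 1,254 higher and 1,269 lower, rested on the spread shared by all 6 groups: with only the 6 HCW libraries concerned in the fit it was 10, and each of the 6 clusters named for this comparison had an adjusted p between 0.085 and 0.178. The count was 1,457 without HCW 0 d library 1, 995 without HCW 1 d library 1 and 1,618 with a stricter filter on low values.

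The HCW comparison of 4 d with 0 d covers the longer exposure. Zinc transporter 5 (Cluster-36310.575) rose from 0.64 ± 0.62 to 35.69 ± 16.83 FPKM, by 4.47 ± 0.35 (adjusted p = 1.97e-05), and ZIP transporters had 18 of 92 members higher and 0 lower, or 33 and 1 adjusted over the list alone (adjusted p = 1.8e-12). TIP1-1 (Cluster-36310.160925) fell by 2.93 ± 0.23, to 82.14 ± 29.72 FPKM, and aquaporins had 5 of 269 higher and 39 lower, or 13 and 62 adjusted over the list alone (adjusted p = 1.04e-09). Glutamate-cysteine ligase (Cluster-36310.42397) rose by 1.26 ± 0.21, from 37.78 ± 5.53 to 92.27 ± 14.36 FPKM. A Glu S.griseus protease inhibitor (Cluster-36310.38148) reached 138.32 ± 64.37 from 0.8 ± 0.17 FPKM. A HIPP26 cluster (Cluster-36310.40041) rose by 4.07 ± 0.42.

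Glutathione synthesis in HCW at 4 d had 6 of 39 members higher and 0 lower, or 9 and 1 adjusted over the list alone (adjusted p = 2.67e-07). Glutathione S-transferases had 47 of 309 higher and 7 lower, or 69 and 13 adjusted over the list alone (adjusted p = 2.21e-06), with member F12 (Cluster-36310.157647) falling by 5.37 ± 0.48. Superoxide dismutases and catalases had 2 of 117 higher and 14 lower, or 8 and 33 adjusted over the list alone (adjusted p = 1.76e-05), and the chloroplastic Cu-Zn enzyme (Cluster-36310.170709) fell by 1.6 ± 0.15. The ascorbate-glutathione cycle had 4 of 165 higher and 1 lower, or 4 and 3 adjusted over the list alone (adjusted p = 0.508), and ascorbate synthesis 2 of 139 higher and 0 lower, or 0 and 0 adjusted over the list alone (adjusted p = 0.761). Flavonoid enzymes had 80 of 351 higher and 10 lower, or 133 and 21 adjusted over the list alone (adjusted p = 3.11e-19). YSL and OPT transporters, which carry metal chelates and peptides, had 13 of 174 higher and 1 lower, or 25 and 2 adjusted over the list alone (adjusted p = 0.000143). Nitrate transporters had 29 of 374 higher and 3 lower, or 42 and 6 adjusted over the list alone (adjusted p = 6.61e-05). Photosynthesis proteins had 0 of 472 higher and 176 lower, or 2 and 268 adjusted over the list alone (adjusted p = 7.91e-64).

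Peroxidase 52 (Cluster-36310.66170) rose by 4.59 ± 0.51 and ERF114 (Cluster-36310.270645) by 4.33 ± 0.42 in HCW at 4 d, while ACC oxidase 1 (Cluster-36310.166036) fell by 4.45 ± 0.49 and lipoxygenase 2 (Cluster-36310.307867), of jasmonate synthesis, by 3.07 ± 0.41. There were 6,125 calls, 2,981 higher and 3,144 lower. The count was 1,855 with only these libraries in the fit, which ended the calls of Cluster-36310.42397 (adjusted p = 0.0621), Cluster-36310.270645 (adjusted p = 0.0624) and Cluster-36310.166036 (adjusted p = 0.0785). For summed proteins it was 3,952, 6.46% of those tested against 2.61% of clusters. Left out singly, HCW 0 d libraries 1 and 2 gave 3,681 and 4,020 calls, and HCW 4 d libraries 2 and 3 gave 3,523 and 3,280.

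**Figure D2:**
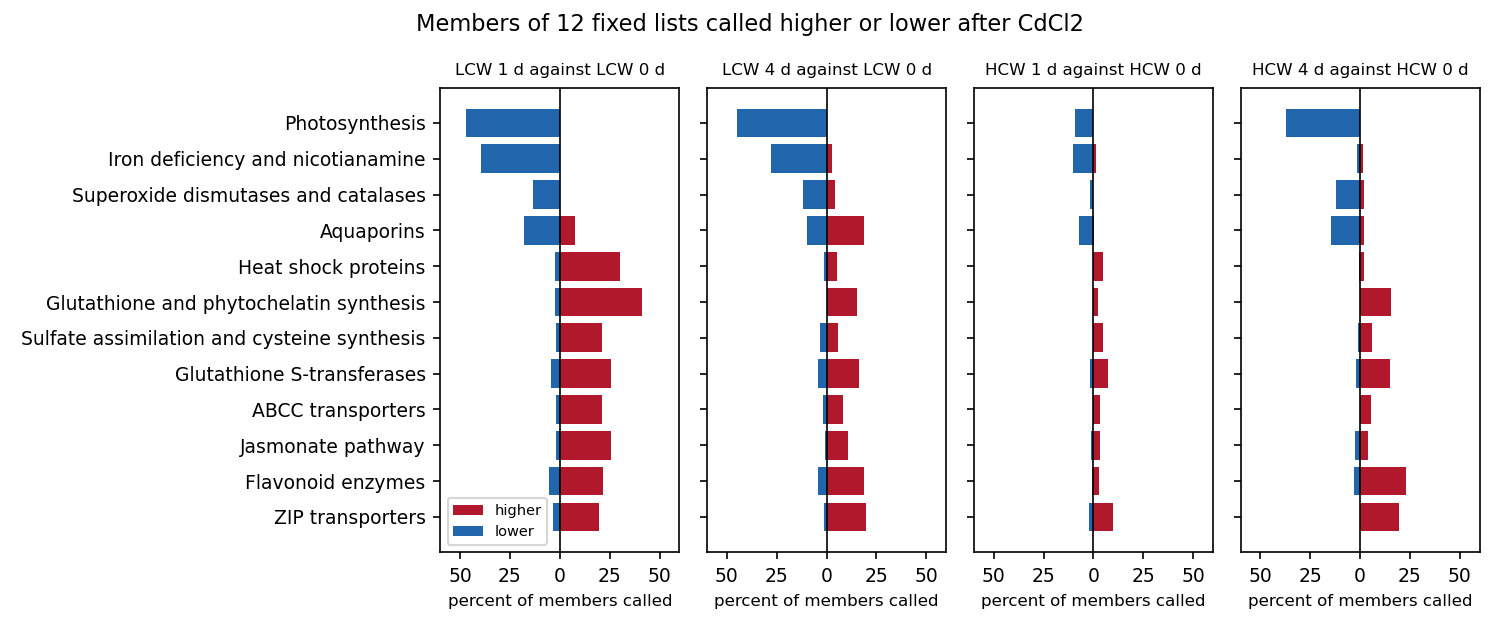
Percent of list members called higher (right) or lower (left) after CdCl2, for 12 lists (rows) in the 4 comparisons with 0 d (panels). Of 472 photosynthesis members, 223 were lower in LCW at 1 d, 213 in LCW at 4 d, 43 in HCW at 1 d and 176 in HCW at 4 d.

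Both genotypes called 732 clusters higher and 560 lower at 1 d, where independent calls would share 64.5 and 66.6. At 4 d they shared 1,497 higher and 1,384 lower, where independent calls would share 89.8 and 95.8. Clusters called in the opposite direction in HCW numbered 4 of those higher and 5 of those lower in LCW at 1 d, and 10 and 7 at 4 d. The LCW and HCW responses use separate 0 d libraries, so these overlaps involve no shared controls. Both use the same estimate of a cluster's spread, however, which favours the same clusters in both. The excess over independent calls therefore does not measure a shared response alone. That spread favours neither direction, so it does not account for the small number of opposite calls. With only the compared groups in each fit, 1 cluster was shared at 1 d, where HCW had 10 calls, and 314 at 4 d. Leaving out HCW 1 d library 1 gave 436 at 1 d, and HCW 4 d library 3 gave 1,581 at 4 d.

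The comparison of the genotypes at 0 d asks how unexposed HCW roots differed from LCW. A dehydroascorbate reductase of the glutathione S-transferase family, DHAR2 (Cluster-36310.306953), was at 40.68, 39.63 and 52.32 FPKM in HCW and listed at 0 in all 3 LCW libraries. The copper chaperone CCH (Cluster-36310.146616) stood at 125.81 ± 25.88 in HCW and 25.05 ± 2.38 FPKM in LCW, higher by 2.27 ± 0.21 (adjusted p = 1.47e-06). A Cu-Zn superoxide dismutase (Cluster-36310.167977) was at 62.22 ± 4.6 in HCW and 132.78 ± 20.47 FPKM in LCW. Lipoxygenase 2 (Cluster-36310.307867) was higher in HCW by 3.15 ± 0.41. A chlorophyll-binding LHCII protein (Cluster-36310.155594) stood at 1.36 ± 0.52 in HCW and 1050.66 ± 529.79 FPKM in LCW.

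Aquaporins at 0 d had 71 of 269 members higher in HCW and 18 lower, or 79 and 23 adjusted over the list alone (adjusted p = 0.000104, and adjusted p = 0.726 with an estimated correlation). Some clusters lost their call once clusters of the same protein were summed. TIP1-1 (Cluster-36310.160925) stood at 613.24 ± 83.23 in HCW and 0.08 ± 0.14 FPKM in LCW, and the summed protein differed by 0.55 (adjusted p = 0.286). RAP2-2, an ethylene response factor, had Cluster-36310.166871 higher in HCW by 4.77 ± 0.28 and Cluster-36310.154254 lower by 2.89 ± 0.21, and a summed difference of 0.38 (adjusted p = 0.304). Mitochondrial superoxide dismutase (Cluster-36310.164320) was at 32.1, 40.45 and 28.15 FPKM in HCW and at 0 in LCW, with a summed difference of 0.23 (adjusted p = 0.313). Photosynthesis proteins had 25 of 472 higher and 60 lower, or 28 and 61 adjusted over the list alone (adjusted p = 0.0189, and adjusted p = 0.854 with an estimated correlation). That list call ended without LCW 0 d library 1 (adjusted p = 0.808), HCW 0 d library 2 (adjusted p = 0.0862) or HCW 0 d library 3 (adjusted p = 0.121), and with land plant hits only (adjusted p = 0.0795). In all 29,028 clusters were called, 14,847 higher in HCW and 14,181 lower, and leaving out bird-hit clusters gave 28,695. Of 61,204 summed proteins 6,135 were called, 10.02% against 12.36% of clusters, and 16,634 clusters were called with these 6 libraries alone in the fit.

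At 1 d the genotypes are compared under exposure. Glutamate-cysteine ligase (Cluster-36310.42397) stood at 72.9 ± 18.78 in HCW and 138.37 ± 20.04 FPKM in LCW, lower in HCW with a change of -0.94 ± 0.21 (adjusted p = 0.00639). Of the HMA5 clusters, Cluster-36310.204559 was higher in HCW, at 41.69 ± 8.72 against 11.87 ± 2.68 FPKM, while Cluster-36310.30311 was at 16.93 ± 5.65 in HCW and 36.0 ± 9.39 FPKM in LCW. Nramp5 (Cluster-36310.98035) was lower in HCW, at 5.19 ± 0.29 against 12.88 ± 2.37 FPKM. Peroxidase 12 (Cluster-36310.171021) was at 310.01, 290.21 and 335.83 FPKM in LCW and listed at 0 in HCW. Heat shock proteins had 17 of 452 members higher in HCW and 114 lower, or 22 and 127 adjusted over the list alone (adjusted p = 4.76e-08, and adjusted p = 0.0897 with an estimated correlation). Sulfate assimilation had 6 of 229 higher and 42 lower, or 9 and 47 adjusted over the list alone (adjusted p = 0.000517, and adjusted p = 0.0897 with an estimated correlation). Photosynthesis proteins had 116 of 472 higher and 15 lower, or 142 and 21 adjusted over the list alone (adjusted p = 0.000854, and adjusted p = 0.66 with an estimated correlation). Calls numbered 35,579, of which 19,111 were higher in HCW and 16,468 lower, but 15,809 and 19,850 with median-ratio scaling and 17,567 and 18,111 with quantile normalization. When summed per protein, 9,878 were called, 16.14% of those tested against 15.15% of clusters. The call of Cluster-36310.42397 ended with these libraries alone in the fit (adjusted p = 0.0572).

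At 4 d, ferric reduction oxidase 4 (Cluster-36310.160755) was at 60.82 ± 7.25 in HCW and 4.53 ± 0.4 FPKM in LCW, higher by 3.48 ± 0.49 (adjusted p = 0.00013). Sulfate transporter 1.2 (Cluster-36310.147405) stood at 100.43 ± 23.02 in HCW and 22.57 ± 4.84 FPKM in LCW. Nramp5 (Cluster-36310.98035) was lower in HCW, at 4.27 ± 0.5 against 11.03 ± 0.64 FPKM, and so was a Cu-Zn superoxide dismutase (Cluster-36310.167977), at 39.05 ± 5.97 against 120.82 ± 9.59 FPKM. Metallothioneins had 6 of 25 members higher and 1 lower, both over all clusters and adjusted over the list alone (adjusted p = 0.00951, and adjusted p = 0.425 with an estimated correlation). YSL and OPT transporters had 25 of 174 higher and 4 lower, or 26 and 4 adjusted over the list alone (adjusted p = 0.00665, and adjusted p = 0.425 with an estimated correlation). Cell division markers had 19 of 643 higher and 137 lower, or 27 and 171 adjusted over the list alone (adjusted p = 7.97e-06, and adjusted p = 0.425 with an estimated correlation). In total 32,663 clusters were called, 16,220 higher in HCW and 16,443 lower (15,985 and 15,965 with quantile normalization), and 8,214 when summed per protein.

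The difference between the genotypes' 1 d responses was tested directly, as the HCW change minus the LCW change. The 18.5 kDa heat shock protein (Cluster-36310.283336) changed less in HCW (adjusted p = 1.02e-05), with 53.54 ± 10.17 FPKM in LCW and 0.39 ± 0.34 FPKM in HCW at 1 d, and was listed at 0 in both at 0 d. Peroxidase 12 (Cluster-36310.171048) rose by 4.43 in LCW, and its HCW change of 1.59 was smaller by a difference of -2.84 ± 0.43. The HIPP26 cluster that appeared in LCW at 1 d (Cluster-36310.38336) was listed at 0 in all 9 HCW libraries, as was cysteine synthase 2 (Cluster-36310.227207). Their differences are the LCW change alone, and another HIPP26 cluster rose in HCW at 4 d. Heat shock proteins had 2 of 452 members with a higher HCW change and 49 with a lower one, or 15 and 87 adjusted over the list alone (adjusted p = 3.74e-06, and adjusted p = 0.0999 with an estimated correlation). Glutathione synthesis had no called member of 39, either way or adjusted over the list alone, and a median difference of -0.688 (adjusted p = 0.000168, and adjusted p = 0.154 with an estimated correlation). Photosynthesis proteins had 45 of 472 with a higher HCW change and 2 with a lower one, or 135 and 5 adjusted over the list alone (adjusted p = 3.67e-12, and adjusted p = 0.293 with an estimated correlation). Limma called 2,539 clusters, 940 with a higher HCW change and 1,599 with a lower one. These numbers were 824 and 2,184 with median-ratio scaling, 777 and 818 when summed per protein, and 1,234 and 1,248 without LCW 0 d library 1 and LCW 1 d library 1. The count was 1,025 with the stricter filter, 1,223 with only the compared groups, 1,385 with a pseudocount of 0.1, 1,684 with limma-voom and 1,310 without HCW 1 d library 2. For summed proteins it was 1,595, 2.61% of those tested against 1.08% of clusters. Limma-voom ended the call of Cluster-36310.171048 (adjusted p = 0.0812).

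At 4 d the difference of responses was called for 762 clusters, 385 with a higher HCW change and 377 with a lower one. These numbers were 707 and 363 without LCW 0 d library 1 and LCW 1 d library 1, and 467 and 274 without LCW 0 d library 2. PIP2-4 (Cluster-36310.145795) differed by -2.64 ± 0.35 (adjusted p = 0.00523): it rose by 2.25 in LCW, and HCW went from 1528.62 ± 467.83 to 1140.24 ± 159.65 FPKM. Aquaporins had 0 of 269 members with a higher HCW change and 28 with a lower one, or 5 and 55 adjusted over the list alone (adjusted p = 6.86e-10, and adjusted p = 0.19 with an estimated correlation). Iron deficiency genes had no called member of 68, either way or adjusted over the list alone, and a median difference of 0.7 (adjusted p = 2.1e-05, and adjusted p = 0.768 with an estimated correlation). The expansin-B2 cluster that rose by 3.99 in LCW (Cluster-36310.324011) was listed at 0 in all 9 HCW libraries, so its difference is the LCW change alone. The count was 212 for summed proteins, 0.35% of those tested against 0.32% of clusters. It fell to 95 with the stricter filter (0.07% of the clusters tested), 329 with land plant hits only, 407 with a pseudocount of 0.1, 451 with replicate numbers as a block and 458 with limma-voom. Left out singly, LCW 4 d libraries 2 and 3 gave 389 and 424 calls, HCW 0 d library 1 gave 471, and HCW 4 d libraries 1, 2 and 3 gave 427, 424 and 396.

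**Figure D3:**
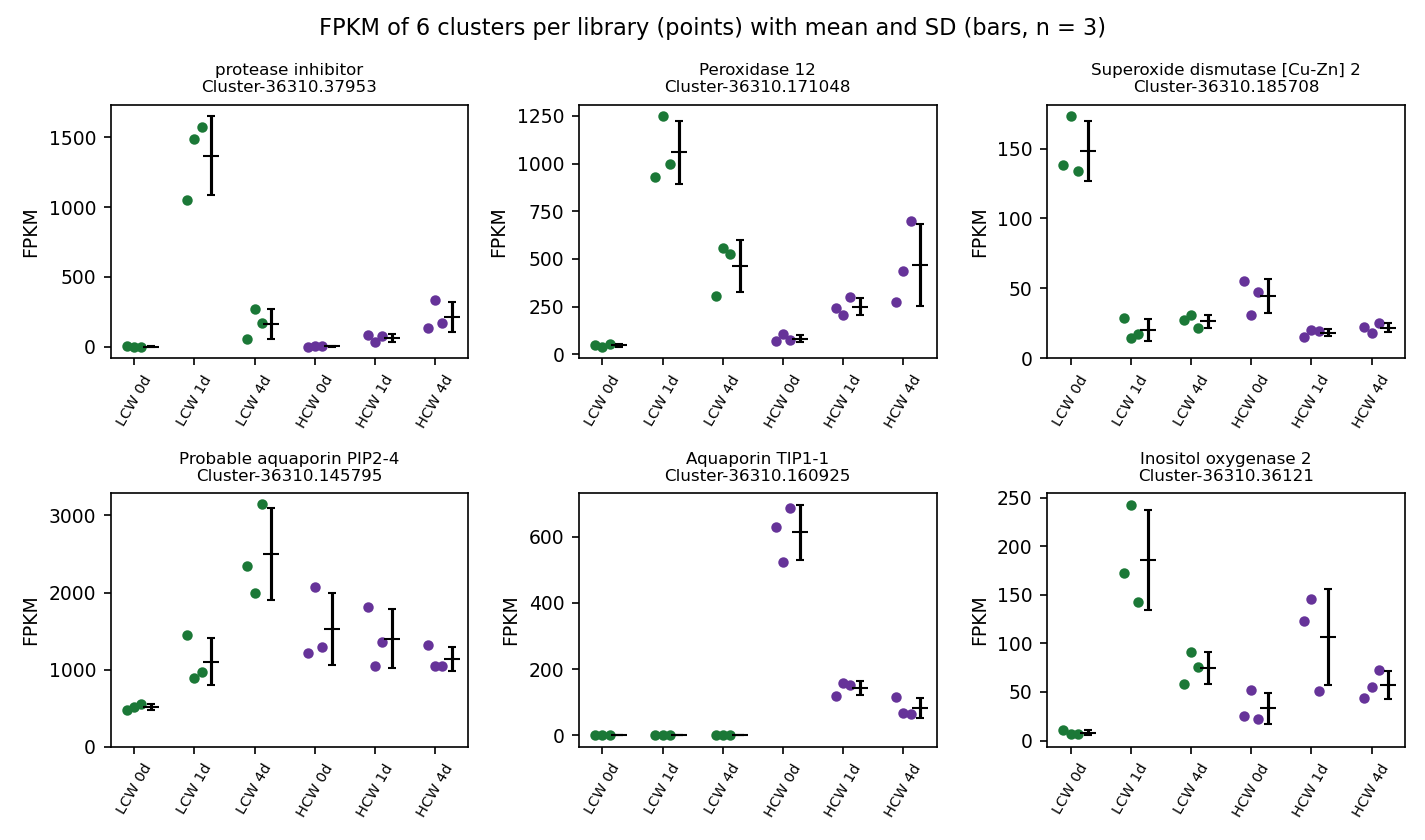
FPKM (vertical axes) of 6 clusters in each of the 18 libraries (points), with the mean and SD of each group of 3 (bars). Peroxidase 12 (Cluster-36310.171048) averages 48.35 in LCW at 0 d, 1058.66 at 1 d and 462.02 at 4 d, and 83.09, 250.94 and 470.15 in HCW.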

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

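The comparison of replicate spread between the genotypes and the splits on values with additive effects removed were chosen only after their results were seen. The clusters and lists flagged first are differences between the genotypes' responses to CdCl2. They were tested as the HCW change minus the LCW change on the log2 scale of FPKM plus 1. The patterns that follow them were not tested in that way.

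At 1 d the test called 2,539 clusters and at 4 d 762. The peroxidase 12 cluster (Cluster-36310.171048) differed by -2.84 ± 0.43, and the hydroxycinnamoyltransferase cluster (Cluster-36310.201909) by 2.4 ± 0.41. The values that follow for clusters listed at 0 in every library of a group are set in size by the pseudocount of 1. The 18.5 kDa heat shock protein (Cluster-36310.283336), at 0 in both genotypes at 0 d, differed by -5.31. The pectinesterase 17 cluster (Cluster-36310.282291), at 0 in HCW at 0 d, differed by -3.49 (-4.15 and adjusted p = 0.1 with a pseudocount of 0.1). Clusters listed at 0 in all 9 HCW libraries differed at 1 d by -5.79 for HIPP26 (Cluster-36310.38336), -3.35 for cysteine synthase 2 (Cluster-36310.227207) and 3.59 for another hydroxycinnamoyltransferase (Cluster-36310.201903). At 4 d such clusters differed by -4.89 for HIPP26 (Cluster-36310.38336) and -3.99 for expansin-B2 (Cluster-36310.324011). Where a genotype lists a cluster at 0 throughout, the value is the other genotype's change alone. Copies of a gene assembled apart in the genotypes could also leave such a 0. Such a cluster alone therefore does not show that the gene's response differed. The reverse case, at 0 in all 9 LCW libraries, gave 6.18 for a protease inhibitor (Cluster-36310.38148), whose summed protein turned to -1.04 (adjusted p = 0.485), and 2.84 for ABCG member 11 (Cluster-53940.2). The last call ended when any 1 library of the 4 groups, apart from HCW 0 d library 2 and HCW 4 d library 3, was left out (adjusted p from 0.0507 to 0.0712), and with a pseudocount of 0.1 (adjusted p = 0.384). TIP1-1 (Cluster-36310.160925), at or below 0.51 FPKM in LCW, differed by -2.19 at 1 d (adjusted p = 0.129 with a pseudocount of 0.1) and -3.26 at 4 d, and its summed protein by 0.16 (adjusted p = 0.889) and -0.9 (adjusted p = 0.532). PIP2-4 (Cluster-36310.145795) differed by -2.64 ± 0.35 at 4 d.

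Some 1 d differences were lost when single libraries were left out, with each lost p the adjusted one from limma. Nramp5 (Cluster-36310.252349), at 0 in HCW at 0 d, differed by 4.64 at 1 d and was not called without LCW 0 d library 2, LCW 0 d library 3 or LCW 1 d library 2 (p from 0.0505 to 0.0549). At 4 d it differed by 4.71 and was not called when any 1 library of the 4 groups, apart from LCW 0 d library 1, was left out (p from 0.0518 to 0.0985). Cu-Zn superoxide dismutase 2 (Cluster-36310.185708) differed by 1.66 and was lost without any 1 library apart from LCW 1 d library 1 and HCW 0 d library 1 (p from 0.0521 to 0.106). Cinnamoyl-CoA reductase 1 (Cluster-36310.257161) differed by -1.94 and was lost without any 1 library apart from LCW 1 d library 1 (p from 0.0508 to 0.104). An ACC oxidase (Cluster-36310.282665) differed by -2.77 and was lost without LCW 1 d library 3 or HCW 0 d library 1 (limma adjusted p of 0.0515 and 0.0508). Inositol oxygenase 2 (Cluster-36310.36121) differed by -2.74 and was lost without LCW 0 d library 2 or 3, LCW 1 d library 2 or HCW 0 d library 2 (p from 0.0555 to 0.0659). The trypsin and hageman factor inhibitor (Cluster-36310.37953) differed by -5.28 and was lost without library 2 or 3 of LCW at 0 d, LCW at 1 d or HCW at 0 d, or library 2 of HCW at 1 d (p from 0.0512 to 0.0648). A thaumatin-like protein (Cluster-36310.39806) differed by -5.47 and was lost without LCW 0 d library 2 or 3, or any 1 library of LCW at 1 d or HCW at 0 d (p from 0.0629 to 0.106). A pseudocount of 0.1 ended the calls of Nramp5 at 1 d (8.03, limma adjusted p = 0.131) and 4 d (7.69, adjusted p = 0.267), Cu-Zn superoxide dismutase 2 (adjusted p = 0.0623), cinnamoyl-CoA reductase 1 (adjusted p = 0.0701), the trypsin and hageman factor inhibitor (adjusted p = 0.195) and the thaumatin-like protein (adjusted p = 0.147).

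The 16 lists whose 1 d responses differed had these median differences: NRAMP transporters 0.281, heavy metal P-type ATPases -0.318, ABCC transporters -0.25, calcium pumps and cation channels -0.195, ascorbate synthesis -0.123, glutathione and phytochelatin synthesis -0.688, sulfate assimilation -0.166, glutathione S-transferases -0.245, thioredoxins with glutaredoxins and peroxiredoxins 0.188, heat shock proteins -0.181, lignin enzymes -0.328, flavonoid enzymes -0.25, jasmonate pathway -0.304, auxin response 0.301, photosynthesis 0.846 and cell division 0.391. For the 5 lists at 4 d the medians were 0.268 for ABCB transporters, -0.458 for aquaporins, 0.7 for iron deficiency genes, -0.225 for ribosomal proteins and -0.269 for cell division. None of these lists was called with an estimated correlation (adjusted p from 0.0999 to 0.769). At 1 d the call of NRAMP transporters ended without HCW 1 d library 1 (adjusted p = 0.058), and that of ABCC transporters without LCW 0 d library 2 (adjusted p = 0.126), HCW 0 d library 2 (adjusted p = 0.0575) or HCW 1 d library 2 (adjusted p = 0.053). That of ascorbate synthesis ended without LCW 0 d library 3 (median 0.004, adjusted p = 0.141), LCW 1 d library 3 (adjusted p = 0.0564), HCW 0 d library 3 (adjusted p = 0.0994) or HCW 1 d library 1 (median 0.022, adjusted p = 0.103). That of thioredoxins ended without LCW 0 d library 1 (adjusted p = 0.0583) or HCW 0 d library 2 (adjusted p = 0.0546), and that of auxin response without LCW 0 d library 1 (adjusted p = 0.075). Without LCW 0 d library 1 the 4 d calls ended for ABCB transporters (adjusted p = 0.152), ribosomal proteins (adjusted p = 0.448) and cell division (adjusted p = 0.729), and each also ended without HCW 0 d library 1 (adjusted p = 0.0539, 0.146 and 0.111), HCW 0 d library 3 (adjusted p = 0.0953, 0.055 and 0.186), HCW 4 d library 1 (adjusted p = 0.0534, 0.0796 and 0.0796) or LCW 4 d library 3 (adjusted p = 0.0796 for all 3). That of ribosomal proteins ended without LCW 0 d library 3 as well (adjusted p = 0.0712).

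The first pattern is that LCW had 24,398 calls at 1 d and HCW 2,523. Thinned to the total of the shallowest library, the LCW count was still 9.54 times the HCW count, which argues against depth. The mean of the median within-group SDs at 0 d and 1 d in HCW was 0.956 times that in LCW. The HCW spread over all clusters was thus not larger, and responding clusters were not examined apart. The main fit uses the same spread for both genotypes, so a larger HCW spread would weigh on both counts there. Comparing 4 d with 1 d gave 15.63 times as many calls in LCW (10,474 and 670). The 0 d libraries do not enter these changes, though they do enter the shared spread and the filter. An LCW excess was thus present in changes that use no 0 d library. That comparison cannot tell how far the LCW 0 d libraries raised the 1 d count. The median absolute change at 1 d was 0.443 in LCW and 0.328 in HCW, while ratios over clusters called in a genotype (LCW over HCW 0.67 for HCW calls, HCW over LCW 0.26 for LCW calls) are pushed down by that choice of clusters and decide nothing. On the second principal component, a main axis of variation between libraries, HCW 1 d library 2 lay at -7.9, and libraries 1 and 3 at -95.4 and -77.9. Library 2 thus lay further toward HCW at 0 d (101.5 to 126.9) than they did, but still nearer its own group. Without it HCW had 2,605 calls (1,528 higher and 1,077 lower), against 18,461 to 21,088 in LCW with 1 library left out. A larger early change in LCW roots may underlie the count, a hypothesis found and tested on the same data. Handling that differed between the genotypes' time points was not recorded and stays open.

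The second pattern is the 29,028 clusters called between the genotypes at 0 d. Of 3000 such clusters, 26.8% had a near-identical cluster called the opposite way, 14.12 times the share among clusters called in LCW at 1 d (1.9%). The summed protein was called in the same direction for 32.2% of those with a protein, against 80.4% in LCW at 1 d. Copies of a gene assembled apart in the genotypes may therefore account for part of these calls. Summing merges only copies with the same best hit, so both such copies and a difference in expression between the genotypes stay open for the 6,135 proteins called when summed.

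The third pattern is the bird-hit clusters in 4 LCW libraries. Across them the 4 libraries correlated with r of 0.722 to 0.773, and of 772 clusters at 1 FPKM or more in LCW 0 d library 1, 82.5 to 88.3% were above 0 in each of the other 3 and at most 6.5% in each of the 14 libraries besides. RNA of another organism in these 4 libraries is a candidate explanation, and when it entered is not known. Of 289 such clusters tested, 180 were called in LCW at 1 d, 253 in LCW at 4 d and 267 between the genotypes at 0 d. No biological explanation was tested.

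Splits of the 6 libraries of a comparison into other groups number 10 with the real one, too few for a share under 0.05, and in each comparison 1 of 10 gave as many calls. The real count and the highest other were 24,398 and 179 for LCW at 1 d, 14,225 and 80 for LCW at 4 d, 2,523 and 81 for HCW at 1 d, and 6,125 and 66 for HCW at 4 d. Between genotypes they were 29,028 and 184 at 0 d, 35,579 and 27 at 1 d, and 32,663 and 22 at 4 d. For the differences of responses, 10 of 100 splits gave as many calls at 1 d (highest other 23,002) and 5 of 100 at 4 d (highest other 21,702), so chance is not excluded by that test. Those splits point to a structure of the samples: all keep the LCW libraries grouped by their time. The highest at each time also keeps the HCW libraries grouped, with their times exchanged, and so calls the response common to both genotypes. The rest mix the HCW times, so their calls take in the LCW change over time. With the additive genotype and time effects taken out, 1 of 100 splits, the real one, gave as many calls at each time. The highest other was 152 at 1 d and 33 at 4 d. These effects were taken out with the real groups, which favours the real split: the splits with 23,002 and 21,702 calls both fell to 0. That test was also chosen after the planned one, so it does not decide about chance.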

How the results depend on the processing

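Limma-voom on rebuilt fragments, median-ratio scaling, the sets without bird-hit clusters or of at least 300 bases, and leaving out LCW 0 d library 1 and LCW 1 d library 1 together were chosen after seeing the data. The planned count-based alternative tool was not run, because the files hold FPKM. Median-ratio scaling, quantile normalization, no filter and the 3 sets left every count within 1.5 times its main value. Single results were less stable under some of them. Testing with no filter ended 18 list calls and 6 named cluster calls. Leaving out LCW 0 d library 1 and LCW 1 d library 1 together ended 8 list calls and 12 named cluster calls. Each of the remaining settings ended at most 2 of either kind. Named clusters had been chosen with at least 300 bases and no bird hit, so those sets could hardly end their calls. Which direction held more calls changed under at least 1 setting in each comparison except the 1 d difference of responses, and scaling alone turned it for LCW at 1 d (14,353 higher and 10,549 lower with median ratios) and the genotypes at 1 d (15,809 and 19,850). Median-ratio scaling moved the median of all clusters from 0.096 to -0.004 for the 1 d difference of responses and from 0.082 to -0.003 for HCW against LCW at 1 d. The stricter filter, which tests fewer clusters, gave 1,618 for HCW at 1 d, and 1,025 and 95 for the differences of responses at 1 d and 4 d. Replicate number as a block gave 451 for the 4 d difference. Residuals of libraries with the same number did not pair (0 of 45 pairs correlated above 0.1, median 0.007, range -0.048 to 0.055, against -0.004 for different numbers), so the block mainly spends degrees of freedom.

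Only the compared groups in the fit, with fewer libraries behind the spread, gave 9,989 for LCW at 1 d, 5,136 for LCW at 4 d, 10 for HCW at 1 d, 1,855 for HCW at 4 d, 16,634 for the genotypes at 0 d, 1,223 for the 1 d difference, and 1 and 314 shared calls at 1 d and 4 d. Land plant hits only gave 329 for the 4 d difference. FPKM summed per protein, with fewer items tested, gave 13,108 and 9,024 for LCW at 1 d and 4 d, 3,952 for HCW at 4 d, 6,135, 9,878 and 8,214 for the genotypes at 0, 1 and 4 d, and 1,595 and 212 for the differences at 1 d and 4 d. The share called rose over that of clusters in LCW at 1 d (21.42% against 10.39%) and 4 d (14.74% against 6.06%) and HCW at 4 d (6.46% against 2.61%). It also rose for the genotypes at 1 d (16.14% against 15.15%) and the differences (2.61% against 1.08% and 0.35% against 0.32%). It fell for the genotypes at 0 d (10.02% against 12.36%) and 4 d (13.42% against 13.91%). A pseudocount of 0.1 gave 1,385 and 407 for the differences, and limma-voom 1,684 and 458. The cause of these last changes was not tested.

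Leaving out each library gave 18,461 to 21,088 calls for LCW at 1 d, 9,388 to 14,312 for LCW at 4 d, 995 to 2,605 for HCW at 1 d, and 3,280 to 5,543 for HCW at 4 d. The genotype comparisons ranged from 23,376 to 29,200 at 0 d, 25,810 to 30,620 at 1 d and 25,294 to 26,592 at 4 d, the differences from 1,310 to 2,696 and from 389 to 741, and shared calls from 436 to 1,468 and from 1,581 to 2,888. Libraries that moved a count by over 1.5 times were LCW 4 d 2 and 3 (9,400 and 9,388), HCW 0 d 1 (1,457 at 1 d, 3,681 at 4 d), HCW 0 d 2 (4,020), HCW 1 d 1 (995), HCW 4 d 2 and 3 (3,523 and 3,280) and, for the 1 d difference, HCW 1 d 2 (1,310). For the 4 d difference they were LCW 4 d 2 and 3 (389 and 424), HCW 0 d 1 (471) and HCW 4 d 1, 2 and 3 (427, 424 and 396). Shared calls moved without HCW 0 d 1 (684 and 1,768), HCW 0 d 2 (1,864 at 4 d), HCW 1 d 1 and 3 (436 and 781) and HCW 4 d 2 and 3 (1,652 and 1,581).

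Of 165 named cluster results, 86 were called under every setting that tested them, 75 were lost in at least 1 and 6 reversed. They had been narrowed to clusters of at least 300 bases without a bird hit, mostly with a protein total called in the same direction. For those 3 settings their stability was therefore largely set by that choice. The reversals came from summing clusters per protein, which adds copies that move the other way: Cluster-36310.154254 became 0.38 at 0 d and 0.55 at 4 d, Cluster-36310.83483 became 0.68 at 4 d and Cluster-36310.160925 -0.35 between genotypes at 4 d, and the differences of Cluster-36310.160925 at 1 d and Cluster-36310.38148 at 4 d became 0.16 and -1.04. Of the list results, 67 were unchanged under every setting with the preset correlation, and the estimated correlation left 29 as they were and ended 72 calls. For the uncalled list of ascorbate synthesis in HCW the test against all other clusters changed direction, which the median need not follow. At 1 d (median -0.013) this came with the stricter filter (median -0.047), summed per protein (-0.044) and without HCW 0 d library 2 (-0.049) or HCW 1 d library 3 (-0.036), and single libraries moved the median from -0.049 to 0.08. At 4 d (median 0.108) it came when summed, where the median turned to -0.019, and without HCW 0 d library 2, where it stayed positive (0.049, with 0.027 to 0.131 over single libraries). Low values limit all of this: in simulated data with 20,000 changed clusters 9% of 2-fold changes under 10 FPKM were called, and with 200 none was.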

Other observations

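Clusters whose best protein hit lies outside land plants, mostly in genera of algae and oomycetes, took 0.15 to 0.6% of the fragments of a library. Of 2,760 such clusters tested, 77 were higher and 459 lower in LCW at 1 d, 343 higher and 497 lower in LCW at 4 d, 3 higher and 169 lower in HCW at 1 d, and 113 higher and 269 lower in HCW at 4 d. Library 1 of LCW at 1 d stood apart from the other libraries of its group, with 0.6% of fragments against 0.25 and 0.2%. The shares were 0.42, 0.29 and 0.32% in LCW at 0 d, 0.3, 0.46 and 0.34% in LCW at 4 d, and 0.15 to 0.31% in the 9 HCW libraries. Such a hit names the nearest database protein, and the organism behind the cluster was not determined.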
